A study of Homo sapiens with 15 samples.

How the data were processed

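Total RNA from quadriceps muscle was sequenced in 15 libraries, 8 labelled ACLR and 7 labelled non-injured; the labels do not spell out the abbreviation ACLR. The table the authors deposited holds whole-number read counts for 58735 genes, as its values show, with 1 column per library. STAR, Partek and DESeq2 are named in the submitters' processing notes, without a role or a version, with the build GRCh38. The read counter, the annotation, the strand setting and the treatment of duplicate reads were not given in the sources used here. All 58735 gene identifiers were found in GENCODE release 29, and the set equals that annotation without its second copies on the Y chromosome, so coordinates are those of that release on GRCh38. Genes of the Y chromosome, XIST and TSIX (520 genes) were taken out before any computation. No column of another sample was present. The labels give no sex, so the comparison of male and female ACLR limbs named in the design text was not made, and the healthy samples of another series were not analysed here.

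Totals ran from 14463499 to 30907005 counts per library. The commonest low count of a gene was 1 or 2 in 8 libraries, 8 in non-injured replicate 1, and between 6 and 16 in the 6 libraries called type B below. Single reads were scarce in these 7 libraries, as when many duplicate reads stand for 1 molecule, so reads are not counted here as independent molecules. Errors given for counts therefore cover the spread between libraries, and no interval for counting error was computed. Without stated strand use, reads of a gene and its antisense partner cannot be told apart, and LINCMD1, which overlaps a microRNA host locus, is uncertain in that sense. HSPA1A and HSPA1B are uncertain for another reason, since their sequences are near-identical.

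Genes were kept by filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 14105 genes, scaled by TMM and tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. The fit used 14 libraries in 7 pairs with the pair as a block; ACLR replicate 3 has no partner and was left out of it. Pairs were read from codes shared by the library names of both groups. No label states that a code is a participant, and the replicate numbers of the titles do not follow the codes, so the pairing is an inference, made before the data were examined, as were the gene lists, the tests and the alternatives unless stated otherwise.

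Whether the codes pair the libraries was checked in several forms, and the outcome was mixed. The correlation of deviations from the group means over 7379 genes ran from -0.44 to 0.74 in same-code pairs, with a mean of 0.10 against -0.01 in other pairs, and exceeded 0.1 in 3 of 7 pairs (exact permutation p = 0.24 over 5040 pairings). After the first axis of variation was removed, a step added on seeing this result, the mean was 0.15 against -0.02 and 5 of 7 pairs exceeded 0.1 (exact permutation p = 0.0056). In 6 genes that were present in some libraries and absent in others, with thresholds set after looking, same-code pairs agreed in 78.6% of cases and other pairs in 48.6% (exact permutation p = 0.0048). The correlation at higher expression limits, that after removing the library type, and the match of genes with bimodal levels were also viewed and are not reported. Not every pair passed 0.1, so values without the block are given beside the results they change.

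A first axis held 50.7% of the variance within groups, and its gene loadings went with transcript length (Spearman rho = -0.57 across genes) and GC content (rho = 0.50); genes are not independent replicates. The labels give no batch. The axis is called technical below because of these correlations, and whether its origin is technical or lies in the tissue was not tested. This axis was measured in 3 ways, all after the data were seen and all reported: first the sign of each library's slope on GC content, then 2 clusters of the libraries' deviations from the group means (types A and B), and last the continuous difference between transcripts under 1000 and over 5000 bases. The first and second place 13 of 15 libraries alike. The GC slope was positive in ACLR replicates 1, 2, 4, 5 and 8 and among non-injured libraries in replicate 6 alone. Its sign therefore went largely with group.

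The 18 gene lists and 10 cell type marker lists were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, with an estimated correlation and fry beside it, and Benjamini-Hochberg adjustment over 28 lists. Some lists share members, so their results are not separate evidence. MYOG and CHRNG are in the denervation and myogenesis lists, C1QC in complement and macrophage, and COL15A1 in basement membrane and fibroblast. The mean log2 ratio of each list's members within each pair (TMM log2 CPM, prior count 2) was tested by a two-sided exact sign-flip permutation test over 7 pairs, whose smallest p is 0.0156. Named genes are the 10 largest rises and 10 largest falls among genes with mean log2 CPM of at least 0, adjusted p under 0.05 and the same direction in at least 6 of 7 pairs, with clone names passed over (3 rises and 4 falls), plus the 3 members with the smallest p and the 3 most abundant members of the lists described by gene. Some items that this rule names are not reported here. DESeq2 1.42.0 and limma voom were alternatives, as were other scalings, filters, blocks and left-out pairs. The technical axis as a covariate, the 3 pairs of one library type and each type alone were added after the data were seen. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Counts were simulated for the ACLR and non-injured libraries, with 13527 genes tested. The edgeR test recovered 86.4% of genes changed 8-fold, 60.0% of those changed 4-fold, 2.1% of those changed 2-fold and 0 of 50 changed 1.5-fold, with 2 false calls. DESeq2 recovered 93.2%, 73.3% and 22.9% of those changed 8-fold, 4-fold and 2-fold and 1 of 50 changed 1.5-fold, with 33 false calls. A list changed 2-fold in the same simulation was recovered with a mean log2 change of 0.99, and 1 other list passed camera. Simulated genes were drawn independently, without pair differences, the first axis or correlation between genes. In the data the estimated correlation within a list reached 0.97, for ribosomal proteins. The simulation therefore does not measure the rate of false calls of the gene or list tests on the data.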

Results

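Gene expression was measured by RNA sequencing in quadriceps muscle of 8 ACLR and 7 non-injured limbs. ACLR libraries held 14972150 to 17565666 counts (n = 8) and non-injured libraries 14463499 to 30907005 (n = 7). Between 13865 and 22562 genes had at least 1 count. The 20 most abundant genes took 30.5% ± 1.23 of the counts in ACLR limbs and 37.8% ± 3.53 in non-injured limbs (SD), and the skeletal muscle actin ACTA1 took 2.90% ± 1.44 and 6.89% ± 1.30. The libraries fell into 2 kinds that differ in the yield of short against long transcripts. Type B, with more short transcripts, held 4 ACLR and 2 non-injured libraries, and type A held 4 ACLR and 5 non-injured libraries.

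**Figure D1:**
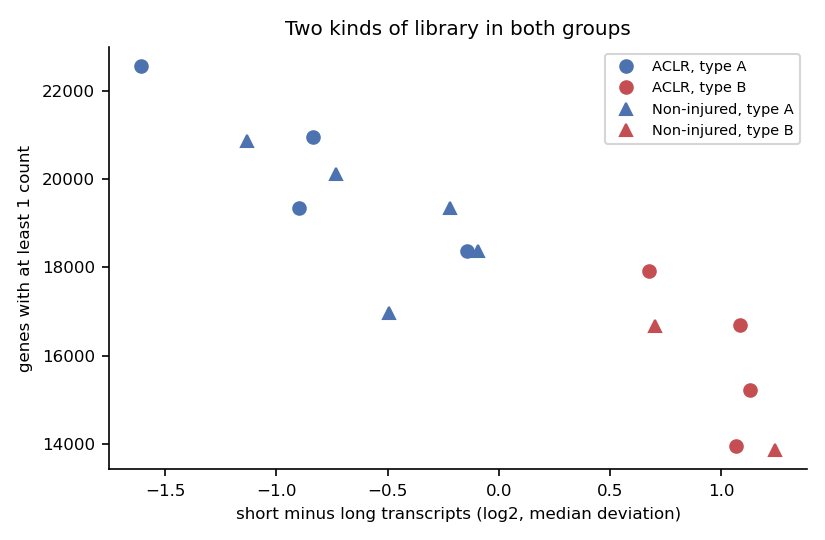
Genes with at least 1 count against the difference between short and long transcripts (log2, median deviation of genes with transcripts under 1000 bases minus that of genes over 5000 bases), 1 point per library, with shape for group and colour for library type. Type B libraries lie between 0.68 and 1.24 and type A libraries between -1.61 and -0.10, with both groups in each type.

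The comparison addressed which genes differ between ACLR and non-injured limbs. Acetylcholine receptor and other denervation-responsive genes were higher in ACLR limbs, while glycolysis and fibroblast genes were lower. Matrix, fast fibre and slow fibre lists were lower at camera's preset correlation but not with an estimated correlation (adjusted p = 0.0833, 0.102 and 0.271). CHRNA1 (ENSG00000138435), the alpha subunit of the muscle acetylcholine receptor, was 20.3-fold higher in the paired fit (group means 397 ± 92.3 against 25.1 ± 24.6 CPM, SD, n = 7 pairs). LDHA (ENSG00000134333; chromosome 11, 18394388 to 18408425), which makes lactate from pyruvate, was 3.96-fold lower (300 ± 103 against 1246 ± 611 CPM). MFAP5 (ENSG00000197614; chromosome 12, 8637346 to 8662888), a microfibril protein of fibroblasts, was 12.5-fold lower (2.00 ± 1.34 against 25.4 ± 14.9 CPM). Of 14105 genes tested by the edgeR quasi-likelihood test with pair as a block, 735 differed at adjusted p under 0.05, 214 higher and 521 lower in ACLR limbs. Of these, 652 changed by over 2-fold and 580 moved the same way in 7 of 7 pairs. Without the block, 1004 genes differed in all 15 libraries, 369 higher and 635 lower, and 653 of the 735 were among them. The count was not stable: it ran from 268 without pair 1 to 2776 without pair 7, with 277 without pair 6, 362 without pair 4, 385 without pair 2, 427 without pair 5 and 466 without pair 8. With the technical axis as a covariate it was 466, 1190 or 1874, depending on how the axis was measured, and of the 735 genes 340, 710 and 735 were called again. Type A libraries alone, without a block, gave 1044 genes and type B libraries alone (4 against 2) gave 42. Scaling by library totals took the median log2 fold change of all genes from -0.01 to 0.30 and turned the split from 29.1% to 78.0% higher, so changes are stated relative to TMM scaling. Of 28 gene and cell type lists, 17 passed camera, 3 higher and 14 lower, and 4 did so with an estimated correlation. With library type from clustering as a covariate as well, none did at an estimated correlation, the smallest adjusted p being 0.0585. The exact sign-flip permutation test over 28 lists lets none pass unless 9 reach its smallest p together: 10 did with TMM scaling, so 10 passed, and 6 did with library totals, so 0 passed. With library totals the denervation (1.44), growth factor (1.37), matrix (-1.19), fast fibre (-1.12) and fibroblast (-1.27) lists kept 1 direction in 7 of 7 pairs, glycolysis (-0.78) and scaffold (-0.55) in 6, and citric acid cycle (-0.15), fatty acid (-0.10) and basement membrane (-0.34) in 5. The endothelial list became 0.58, higher in 7 of 7 pairs.

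The largest rises among named genes were in CHI3L1, a secreted chitinase-like glycoprotein on chromosome 1 (203178931 to 203186749, GRCh38), with a log2 fold change of 6.88 ± 0.97 (SE; edgeR adjusted p = 0.00249), and in the noncoding MIR503HG (5.78 ± 0.92, adjusted p = 0.00538). CHRNA1 on chromosome 2 (174747592 to 174787935) rose by 4.34 ± 0.38 on this scale, the muscle noncoding RNA LINCMD1 by 4.12 ± 0.59, and ANKRD1, a stretch-responsive muscle ankyrin repeat protein, by 3.96 ± 0.44. NRXN3, KRT80, LENG9 and TMEM238 rose by between 4.06 and 4.40. The largest falls were in ACTN3, the alpha-actinin of fast fibres (-6.55 ± 0.65, adjusted p = 0.000893), SMCO1 (-6.43 ± 0.77), the matricellular CCN3 (-6.31 ± 0.65), the lubricating proteoglycan PRG4 (-5.99 ± 1.15), PCOLCE2 (-5.97 ± 0.71) and AQP4, the water channel of fast fibres (-5.50 ± 0.88). FNDC1, ASB18, LRRC37A7P and METTL21EP had log2 fold changes of -5.28, -5.20, -5.08 and -5.04. ACTN3 varied widely in non-injured limbs (1527 ± 1476 CPM, SD, n = 7). Several leading genes lay near the floor in 1 group. PRG4 had no count in 5 of 7 ACLR libraries, ASB18 and LRRC37A7P in 4, and CCN3, PCOLCE2 and FNDC1 in 3. NRXN3 had no count in 4 of 7 non-injured libraries, and CHI3L1, MIR503HG and LENG9 in 3. The sizes and ranks of these changes are uncertain for that reason. Of the 19 genes named here, 14 passed in each alternative recomputed for them (13 or 14 per gene), and NRXN3, KRT80, LENG9, TMEM238 and ASB18 did not. In the 3 pairs of one library type, 11 of those 14 passed, and PRG4, FNDC1 and LRRC37A7P did not (adjusted p = 0.202, 0.119 and 0.0982). Without the block NRXN3, TMEM238 and ASB18 did not pass (adjusted p = 0.101, 0.0711 and 0.0853).

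Denervation and neuromuscular junction genes were higher as a group. Of 19 tested, 9 rose and 1 fell over all genes tested, and adjusted over the list alone 10 rose and 3 fell. Besides CHRNA1, the transcription factor RUNX1 rose by 3.18 ± 0.39 (SE), GADD45A, induced by denervation and stress, by 3.20 ± 0.39, the myogenic factor MYOG by 2.04 ± 0.31 and the receptor subunit CHRNB1 by 1.12 ± 0.22. The list's mean log2 ratio was 1.14 ± 0.47 (SD, 7 of 7 pairs higher; exact sign-flip p = 0.0156, adjusted 0.0437), and camera gave an adjusted p of 3.46e-06, with an adjusted p of 0.0277 at the estimated correlation. In the 3 pairs of one library type the mean was 1.07. The satellite cell and myogenesis list did not pass (0.42 ± 0.44, camera adjusted p = 0.0685) except with the technical axis as a covariate (0.0343, 0.0129 and 0.0458 by clustering, GC slope and the continuous measure) and without pair 1 (0.0309) or pair 4 (0.0271), although MYOG and the fetal receptor subunit CHRNG (2.81 ± 0.50) rose. Both of these, MYOG and CHRNG, are also members of the denervation list. MYOD1 stood at 1.92 ± 0.51 (adjusted p = 0.0509, and 0.0206 without the block) and MYF6 at 0.58 ± 0.26 (adjusted p = 0.243). Of 11 growth factor and injury genes, 2 rose (6 higher and 1 lower adjusted over the list alone), TGFB3 (2.68 ± 0.29) and ANKRD1. That list's mean change was 1.08 ± 0.39 (SD, 7 of 7 pairs; camera adjusted p = 0.00217), with adjusted p = 0.0696 at an estimated correlation. CDKN1A, a cell cycle inhibitor, had a log2 fold change of 3.15 ± 0.92 that did not pass (adjusted p = 0.0722, and 0.0359 without the block), CSRP3 one of -1.80 ± 0.59 (adjusted p = 0.104) and XIRP1 one of -0.12 ± 0.28.

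**Figure D2:**
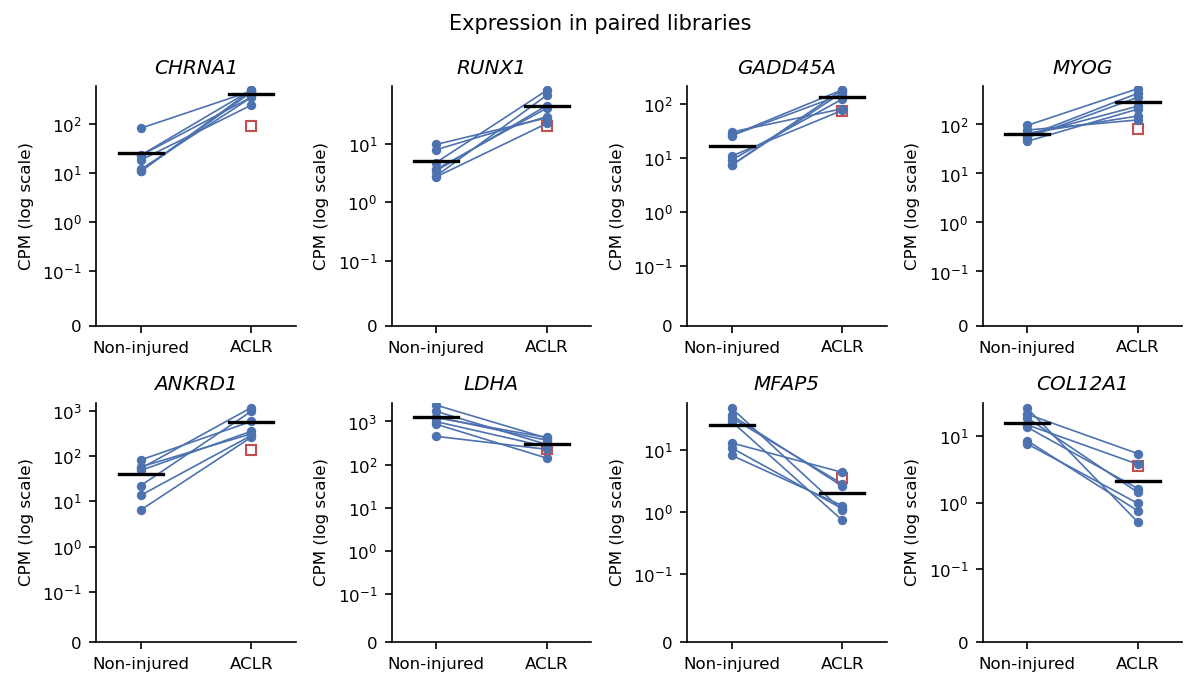
Normalised expression (CPM, log scale that is linear below 0.1) of 8 genes in the 7 pairs, joined by lines, with the mean of each group as a black bar and the ACLR library without a partner as an open square. CHRNA1 averaged 25.1 CPM in non-injured and 397 CPM in ACLR limbs, and MFAP5 25.4 and 2.00 CPM.

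Among energy metabolism lists, glycolysis and the citric acid cycle were lower with an estimated correlation as well, and the fatty acid and respiratory chain lists were not. Of 19 glycolysis and glycogen genes, 11 fell and 0 rose (16 lower adjusted over the list alone), with a mean change of -1.09 ± 0.27 (SD, 7 of 7 pairs lower, exact sign-flip adjusted p = 0.0437; camera adjusted p = 3.86e-12, and 0.0277 with an estimated correlation). Lower members were LDHA (-1.98 ± 0.27), enolase ENO3 (-1.91 ± 0.37), the phosphorylase kinase subunit PHKG1 (-1.82 ± 0.28), glycogen phosphorylase PYGM (adjusted p = 0.0095) and GAPDH (-1.14 ± 0.28). In the 3 pairs of one library type the mean change was -1.32. The citric acid cycle list changed by -0.47 ± 0.09 (SD, 7 of 7 pairs lower; camera adjusted p = 0.000517, and 0.046 with an estimated correlation), with 1 member lower over all genes tested (1 higher and 6 lower adjusted over the list alone), IDH2 (-1.07 ± 0.25). DLST (-0.65 ± 0.19), MDH2 (-0.37 ± 0.28) and OGDH (-0.16 ± 0.24) did not pass. With library type from clustering as a covariate 5 members were lower, DLST and MDH2 among them. In the fatty acid list 2 of 20 fell (6 lower adjusted over the list alone), HADH (-1.41 ± 0.25) and ETFDH (-0.87 ± 0.22), and its mean change was -0.41 ± 0.19 (SD; camera adjusted p = 0.0242, and adjusted p = 0.102 with an estimated correlation). ACADM (-1.28 ± 0.34), ACADVL (0.53 ± 0.31), PDK4 (-1.28 ± 0.83) and HADHA (0.03 ± 0.22) did not pass; without the block ACADM did (adjusted p = 0.0433). Of 30 nuclear-encoded respiratory chain genes, 1 fell (0 adjusted over the list alone), ATP5MC3 (-0.88 ± 0.23). Their mean change was -0.27 ± 0.61 (SD, 4 of 7 pairs lower), with a camera adjusted p of 0.00755 that became an adjusted p of 0.475 with an estimated correlation, and with library totals the mean was 0.05. ATP5F1A (-0.68 ± 0.22), UQCRC2 (-0.60 ± 0.21), ATP5F1B (-0.59 ± 0.22) and UQCRC1 (-0.17 ± 0.30) did not pass, but without the block ATP5F1A and ATP5F1B did (adjusted p = 0.0311 and 0.0412).

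Contractile and scaffold genes were lower in part. Fast fibre genes had 5 of 14 members lower (7 adjusted over the list alone) and a mean change of -1.42 ± 0.71 (SD, 7 of 7 pairs; camera adjusted p = 1.2e-06, and adjusted p = 0.102 with an estimated correlation). Besides ACTN3, the calcium pump ATP2A1 (-2.35 ± 0.29) and the light chain MYL1 (-2.35 ± 0.32) fell, while MYH2 (-1.17 ± 0.36), TNNC2 (-0.02 ± 0.55) and TNNT3 (-0.26 ± 0.49) did not pass. Slow fibre genes had 4 of 11 lower (5 adjusted over the list alone), among them MYH7B (-2.78 ± 0.55), MYL3 (-2.43 ± 0.59) and CASQ2 (-1.78 ± 0.41), with a mean change of -1.21 ± 1.29 (SD, 5 of 7 pairs lower; camera adjusted p = 4.68e-05, and adjusted p = 0.271 with an estimated correlation). In the 3 pairs of one library type the means were -1.84 for fast and -2.09 for slow fibre genes. With the technical axis as a covariate by clustering, GC slope or the continuous measure, the mean log2 fold change of slow fibre genes went from -1.20 to -1.60, -1.59 or -1.40, and the adjusted p of MYH7 was 0.00404, 0.0764 or 0.00913. MYH7 (-1.66 ± 0.47), TNNI1 (-0.93 ± 0.55) and TNNT1 (0.31 ± 0.58) did not pass in the paired fit. With library type from clustering as a covariate 10 of 11 slow fibre genes were lower, TNNI1 among them (edgeR adjusted p = 0.0115), and 7 of 14 fast fibre genes. With an estimated correlation the camera adjusted p of the slow fibre list was then 0.115. Without the block MYH2 and MYH7 passed (adjusted p = 0.0336 and 0.0444). Of 12 sarcomere scaffold genes 4 fell (6 adjusted over the list alone), including MYOT (-2.96 ± 0.43), MYOM2 (-1.57 ± 0.25) and ACTA1 (-1.85 ± 0.37), with a mean change of -0.87 ± 0.33 (SD, 7 of 7 pairs; camera adjusted p = 8.27e-05, and adjusted p = 0.102 with an estimated correlation). CKM (-0.94 ± 0.34) and DES (0.01 ± 0.41) did not pass.

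Matrix and fibroblast genes were lower. Of 24 collagen and extracellular matrix genes 10 fell and 0 rose (17 lower adjusted over the list alone), with a mean change of -1.48 ± 0.67 (SD, 7 of 7 pairs lower; camera adjusted p = 3.86e-12, and adjusted p = 0.0833 with an estimated correlation). Those lower included COL12A1 (-3.19 ± 0.44), fibronectin FN1 (-2.14 ± 0.31), the gelatinase MMP2 (-1.73 ± 0.24) and COL6A1 (-1.09 ± 0.26). In the 3 pairs of one library type the list mean was -1.30. COL6A2 (-0.74 ± 0.37) and SPARC (0.49 ± 0.26) did not pass. Of 13 fibroblast and fibro-adipogenic progenitor markers 8 fell (10 adjusted over the list alone), with a mean change of -1.57 ± 0.53 (SD, 7 of 7 pairs lower; camera adjusted p = 2.84e-10, and 0.0277 with an estimated correlation). The mean over the 3 pairs of one type was -1.66. Lower members included MFAP5 (-3.64 ± 0.47), FBLN2 (-1.78 ± 0.32) and the proteoglycan DCN (-1.46 ± 0.26). GSN (-0.89 ± 0.32), IGFBP5 (-0.85 ± 0.39) and CFD (-0.75 ± 0.43) did not pass. Of 16 macrophage markers 2 fell (3 adjusted over the list alone), CSF1R (-1.71 ± 0.38) and C1QC (-2.00 ± 0.51), with a mean change of -1.14 ± 0.92 (SD; camera adjusted p = 0.00221, and adjusted p = 0.317 with an estimated correlation). LYVE1 (-3.53 ± 0.96), CD74 (0.06 ± 0.22), HLA-DRA (-0.24 ± 0.24) and CD14 (-0.55 ± 0.43) did not pass, but without the block LYVE1 did (adjusted p = 0.0145). Endothelial markers had a mean change of 0.26 ± 0.41 (SD, 5 of 7 pairs higher; camera adjusted p = 0.0721), with 0 of 12 past the edgeR threshold; CLDN5 (1.08 ± 0.42), EGFL7 (1.05 ± 0.47), TIE1 (0.42 ± 0.22), VWF (0.35 ± 0.25) and AQP1 (0.33 ± 0.24) are its leading and most abundant members.

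**Figure D3:**
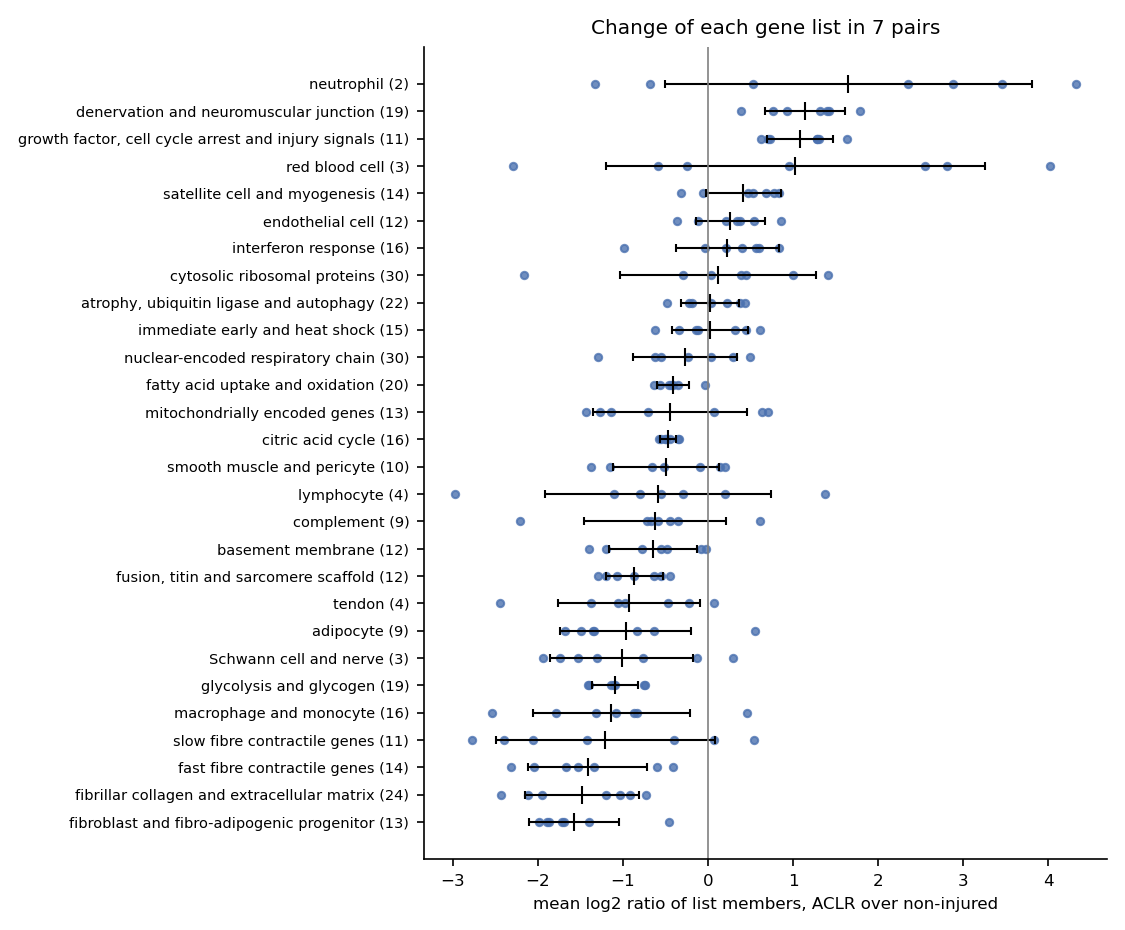
Mean log2 ratio (ACLR over non-injured) of the members of each gene list, 1 point per pair, with the mean and SD over 7 pairs as a black mark and bar and the number of members tested in brackets. The denervation list averaged 1.14 and the fibroblast list -1.57, each on one side of 0 in 7 of 7 pairs.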

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

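Of the tests below, that of the technical axis as a covariate was chosen after the result was seen, and so was the condition that leaves the nerve sheath test undecided; the tests in the 3 pairs of one library type were chosen after the data were seen. A value apart from the rest of its group was found in 6 of 62 sets of values, where chance gives about 1 in 20. Non-injured replicate 1 held 30.91 M counts against 14.46 to 20.54 M in the other non-injured libraries. Haemoglobin genes took 0.359% of counts in ACLR replicate 2 and 0.030% to 0.044% in the other ACLR libraries. The fibroblast list changed by -0.46 in pair 8 against -1.98 to -1.40 in the other pairs. In pair 7 the log2 ratio was 0.55 for LENG9 (3.06 to 4.24 elsewhere) and 8.46 for LINCMD1 (2.58 to 4.96 elsewhere), and in pair 5 it was -6.87 for PCOLCE2 (-5.36 to -4.33 elsewhere). LINCMD1 had 0 CPM in the non-injured library of pair 7, and 42.1 CPM in its ACLR library against an ACLR mean of 47.1. PCOLCE2 had 0 CPM in the ACLR library of pair 5, so both ratios depend on the prior count. In the ACLR library without a partner, which is not in the paired fit, 16 of the 20 leading genes lay beyond all 7 non-injured libraries in the direction found in the pairs. Those genes were chosen for their difference from the same 7 libraries, and how many would lie beyond them without a change was not computed, so this is not an independent test.

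The number of genes that differed was weighed against chance and against the technical axis. Of the 64 ways to exchange the limbs within pairs, 2 gave at least 735 genes, the real one included, and the other, with pair 7 exchanged, gave 2143. The share is under the 0.05 set beforehand against chance. The test takes the inferred pairs as given, and 1 false grouping called more genes than the real one. It therefore argues against chance only if the pairing holds. The exchange of pair 7 puts 11 of 14 libraries where their type would, against 9 in the real grouping. The 7 other exchanges that do so gave 0 genes each. Each of them exchanges 2 or more pairs, so they cannot separate library type from the ACLR difference. In pair 7 the ACLR library is of type A and the non-injured one of type B. The 3 other pairs of mixed type are the other way round, so exchanging pair 7 aligns type with group among the mixed pairs. Whether library type or another trait of pair 7 gives the larger count was not tested. In pair 7 as labelled the denervation (0.77), glycolysis (-0.74) and fibroblast (-1.98) lists changed in the direction of the other pairs. These are lists that kept 1 direction in 7 of 7 pairs, and not every list did so. The ribosomal list changed by -2.17 in pair 7 and by -0.29 to 1.41 in the other pairs. The median over all exchanges but the real one was 0 genes. A further 36 splits, drawn at random and leaving at least 1 pair unparted, gave at most 460. With the axis as a covariate, in the least favourable of 3 ways of measuring it, 99.0% of the 735 genes kept their sign and at least 0.5 of their size. All 735 moved the same way in at least 6 of 7 pairs, and the clustered type differs within 4 pairs only. Much of this result was therefore set by how the genes were chosen, and it is not counted against the axis. How many genes pass stays open, since the 3 ways gave 466, 1190 and 1874. Of the 735 genes they called 340, 710 and 735 again.

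The rise of denervation genes held in the 3 pairs whose libraries are of one type, with a mean change of 1.07 and each of the 3 above 0. That argues against the clustered library type as its cause. Those pairs, 1, 5 and 6, are set by the clustered types, and pairs 5 and 6 each hold a library whose name carries a suffix. The sign of the GC slope leaves 1 pair of one type. In pairs 1, 5 and 6 the ACLR library had the higher slope (0.024 against -0.091, 0.222 against -0.042 and -0.202 against -0.262). These pairs are therefore not matched on that measure. With that sign as a covariate the mean log2 fold change of the denervation list was 1.12. More nerve sheath tissue in ACLR samples was not decided: the Schwann cell and nerve list changed by -1.02, which met the value written beforehand against it, but 3 of its 10 members were tested, and of these PMP22 is not specific to nerve. A response of the fibres themselves to altered innervation or loading remains an untested hypothesis.

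The fall of matrix genes held in those 3 pairs, at -1.30, which argues against the clustered library type as its cause. Those pairs are not matched on the GC slope. With the sign of that slope as a covariate the mean log2 fold change of the matrix list was -1.39. Whether a general loss of non-muscle cells accounts for it was not decided. The endothelial list changed by 0.26 with an SE of 0.154, above 0 by more than its SE. That met the value written beforehand against such a loss, but the list's exact sign-flip p was 0.141. Its camera adjusted p was 0.0721, and with the axis as a covariate 0.0497 by clustering, 0.0943 by GC slope and 0.0282 by the continuous measure. By contrast, the smooth muscle and macrophage lists changed by -0.49 and -1.14. The adipocyte, Schwann cell, tendon and lymphocyte lists also fell (-0.97, -1.02, -0.93 and -0.59), while the red blood cell and neutrophil lists stood at 1.03 and 1.65. A smaller share of fibroblasts or lower expression in them both stay open.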

How the results depend on the processing

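The covariates for the technical axis, the 3 pairs of one library type and each type alone were chosen after the data were seen; the other alternatives were not. No gene called in the paired fit reversed in the settings run for the 108 genes recomputed. In 1247 gene and setting combinations the call and direction held, in 133 the gene no longer passed, in 88 it newly passed and in 41, for genes not called, the sign changed. Of the leading genes, NRXN3, KRT80, LENG9, TMEM238 and ASB18 missed the threshold in some of the 13 or 14 alternatives recomputed for each, with highest adjusted p of 0.185, 0.115, 0.23, 0.188 and 0.147. Other called list members also missed it in some of 14 alternatives. ETFDH, C1QC, COL15A1, BNIP3L and ZFP36 did so in 7, and COL6A1, ATP5MC3, GAPDH and ACVR2B in 6. IDH2, CASQ2, FBXO40 and CSF1R did so in 5, MYL3 and PLIN1 in 4 and IRF7 in 3. For CHRNB1, MYH7B and PMP22 it was 2, and for ACTA1 1. The number of genes past the threshold, 735, depended strongly on the setting; where the construction does not show why, the cause was not tested. At this size of study the simulated test recovered few 2-fold changes, so genes not called are not shown to be unchanged.

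Without a replicate block 1004 genes differed in all 15 libraries, 369 higher and 635 lower. With the title's replicate number as the block 413 differed (102 higher, 311 lower), and with the pair as a random effect in limma voom 1196 (396 and 800); the within-pair correlation was 0.072. DESeq2 called 2056 genes (806 and 1250) and limma voom 1113 (406 higher). On simulated data DESeq2 made more false calls than edgeR and also recovered more of the changed genes. Library totals gave 1360 (1061 and 299) and took the median log2 fold change from -0.01 to 0.30. With them 0 lists passed the sign-flip test, which needs 9 lists at its smallest p for any to pass; 6 reached it. No filter on low counts, which tests more genes, gave 1454 (557 and 897). Leaving out the pairs with a library whose name carries a suffix, which leaves 5 pairs, gave 84 (19 and 65). The pairs left out, 5 and 6, are of one library type each, so 4 of the 5 pairs left are of mixed type. The fall in number cannot be assigned to the suffix or to library type. With the axis as a covariate the counts were 466 by GC slope (130 and 336), 1190 by clustering (390 and 800) and 1874 by the continuous measure (801 and 1073). Without a block, type A alone gave 1044 (322 higher), type B alone 42 (17 and 25), with 6 libraries, and all 15 libraries with the clustered type as a covariate 1656 (667 and 989). Leaving out 1 pair gave 268 to 2776 genes, 65 to 1476 higher and 203 to 1300 lower, lowest without pair 1 and highest without pair 7, and 12 to 20 lists past camera. Of 28 lists, 4 passed camera with an estimated correlation and 11 passed fry, against 17.

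Without pair 7 the respiratory chain (0.232), fatty acid (0.0796), macrophage (0.0851), adipocyte (0.232) and Schwann cell (0.0851) lists lost their camera call. Calls were also lost for mitochondrially encoded genes without pair 1 (0.126), 2 (0.0947) or 8 (0.201), neutrophil without pair 2, 4, 5, 6 or 7 (0.0712 to 0.283), adipocyte without pair 6 (0.0589) or 8 (0.079) and Schwann cell without pair 1 (0.263). Calls were gained for endothelial genes without pair 5 (0.0366) or 8 (0.0311), smooth muscle without pair 4 (0.0265), 5 (0.0489) or 6 (0.0388), interferon and red cell without pair 5 (0.0391 and 0.0122) and ribosomal genes without pair 7. Reversals concerned results that had not passed the test they belong to; the respiratory chain list had passed camera and not the sign-flip test. The ribosomal list turned lower with each covariate (adjusted p = 0.00193 by clustering, 5.5e-06 by GC slope and 0.0219 by the continuous measure) and without pair 2 (0.391) or pair 4 (0.839), over a range of 7.4e-05 to 0.839 without 1 pair. The lymphocyte list turned with the GC slope (0.7) and without pair 5 (0.894; range 0.509 to 0.894), and the atrophy list without pair 1 (0.979; range 0.388 to 0.979). The respiratory chain mean became 0.05 with library totals, and the immediate early mean -0.03 with a prior count of 0.5. Among genes (log2 fold change), without a block XIRP1 was 0.07. FBXO32 was -0.02 and DES -0.01 with DESeq2 and with its size factors in edgeR, and with voom DES was -0.01. By clustering, GC slope and the continuous measure, TNNT1 was -0.35, -0.56 and -0.07, DES -0.40, -0.64 and -0.23, and CD74 -0.08, -0.13 and -0.01. HADHA was -0.05 by clustering and -0.02 by the continuous measure. By GC slope DNAJB1 was 0.11, HLA-DRA 0.03, IGFBP5 0.01 and AQP1 -0.04. Over the 7 fits without 1 pair, log2 fold changes that crossed 0 were UQCRC1 -0.37 to 0.02, HADHA -0.08 to 0.12, TNNT1 -0.08 to 0.73, TNNC2 -0.36 to 0.42, TNNT3 -0.59 to 0.11 and FBXO32 -0.21 to 0.14. Others that did so were XIRP1 -0.26 to 0.06, HSPA1A -0.22 to 0.07, DNAJB1 -0.23 to 0.08, DES -0.24 to 0.30 and CD74 -0.09 to 0.15. The cause was not tested for these reversals.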

Other observations

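Single regulators moved within lists that did not move as a whole. The atrophy, ubiquitin ligase and autophagy list had a mean change of 0.02 ± 0.34 (SD, 7 pairs). In it FBXO40, a muscle ubiquitin ligase subunit, fell by 1.87 on the log2 scale, the activin receptor ACVR2B fell by 1.65 and the mitophagy receptor BNIP3L rose by 0.88. These calls were not stable and were lost in 5, 6 and 7 of the 14 alternatives recomputed for each. FBXO32 stood at 0.00 ± 0.33, SQSTM1 at 0.73 ± 0.34 and the metallothionein MT2A at 2.76 ± 0.85, none past the threshold. Among immediate early and heat shock genes (mean change 0.02 ± 0.45) NR4A1 (-2.62 ± 0.43) and ZFP36 (-1.16 ± 0.26) fell while MYC rose by 1.86, and JUN (1.00 ± 0.31), HSPA1A (-0.10 ± 0.26) and DNAJB1 (-0.09 ± 0.26) did not pass. ZFP36 did not pass in 7 of its 14 alternatives, among them the fit without the block (edgeR adjusted p = 0.138). Among interferon response genes (0.23 ± 0.61) IFIT1 fell by 2.28 and IRF7 rose by 2.47, and ISG15 (1.54 ± 0.64) and B2M (0.30 ± 0.23) did not pass.

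The basement membrane list changed by -0.64 ± 0.52 (SD, 7 pairs; camera adjusted p = 0.000575, and 0.186 with an estimated correlation) with 1 member lower, COL15A1 (-0.93 ± 0.22 SE). The adipocyte list changed by -0.97 ± 0.77 (camera adjusted p = 0.0398, and 0.396 with an estimated correlation) with 1 lower, PLIN1 (-2.15 ± 0.49), and complement by -0.62 ± 0.83 with 1 lower, C1QC; the complement list did not pass camera (adjusted p = 0.0586) except without the block (0.0174), with the technical axis as a covariate (0.00814, 0.0034 and 0.0219) and without pair 2 (0.0348), 6 (0.0377) or 8 (0.00844). Schwann cell and nerve had 1 lower, PMP22 (-1.25 ± 0.24; list camera adjusted p = 0.025, and 0.189 with an estimated correlation); without the block PMP22 did not pass (adjusted p = 0.164). No member passed among mitochondrially encoded genes (-0.45 ± 0.91), cytosolic ribosomal proteins (0.12 ± 1.16), smooth muscle (-0.49 ± 0.62), tendon (-0.93 ± 0.84), lymphocyte (-0.59 ± 1.33), red blood cell (1.03 ± 2.23) and neutrophil (1.65 ± 2.16) genes. Of these, the mitochondrially encoded and neutrophil lists passed camera (adjusted p = 0.0332 for each) but not with an estimated correlation (0.502 and 0.261), and the neutrophil list did not pass without the block (0.468). Both moved with the technical axis, as did the ribosomal list. With the axis as a covariate by clustering, GC slope or the continuous measure, the mean log2 fold change of mitochondrially encoded genes went from -0.49 to -0.18, -0.03 or -0.30, and their call was lost with the first and second (0.17 and 0.951). That of neutrophil genes went from 2.04 to 1.54, 0.69 or 1.62, with the call lost in each (0.0965, 0.471 and 0.0661), and that of ribosomal genes from 0.17 to -0.28, -0.55 or -0.14. The respiratory chain list moved further from 0, from -0.26 to -0.49, -0.63 or -0.40, with camera adjusted p of 6.63e-10, 6.73e-10 and 2.25e-09. By clustering 7 members were lower instead of 1, but with an estimated correlation the camera adjusted p by clustering was 0.115. The respiratory chain list changed by -0.47 in the 3 pairs of one library type, against -0.27 in all 7.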
